A study of Micropterus salmoides with 8 samples.

How the data were processed

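Ovarian RNA of 8 female largemouth bass (Micropterus salmoides, a North American freshwater sport fish) collected in April was measured on Agilent 1-colour oligonucleotide arrays, 1 array per fish. Per the labels, 4 fish came from the St John River and 4 had been placed in Apopka mesocosms, which are enclosures that hold a part of a lake or pond under outdoor conditions. Total RNA was extracted with the STAT60 protocol and labelled with Cy3, per the labels' protocols. The labels state no ovarian stage, fish age, body size, chemical or exposure time in words, and they do not tie fish of the groups to each other. The titles of the 4 river fish carry the prefix eOM, which those of the mesocosm fish lack and which the labels do not explain.

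Each scanner file holds 15744 spots, of which 536 are control spots and 15208 are probes of 60 bases with 1 spot each. The spot values are fluorescence intensity written by Agilent Feature Extraction 10.1.1.1, which subtracted the local background and a spatial trend, removed a multiplicative trend and put surrogate values on dim spots, per the file headers. The deposited intensity values were not normalized between arrays. The authors' series matrix was deposited as log2 values. Its rank correlation with the scanner signal of the same array was between 0.99936 and 0.99997, and the medians of its columns were between 8.86 and 8.96, so that the arrays had been brought to nearly equal distributions. The method behind it is not given in the sources used here, and its scale is log2 with no centring of probes.

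The deposited probe names are those of contigs (13699 probes) or of clones, added sequences and accessions. All 15208 descriptions read unknown. A reference gene table of assembly ASM1485139v1 with 37622 genes held 0 of the probe names, and 0 probe names met any of the 29 gene lists fixed before the data were examined. Genes could therefore not be named here, no genome position is given, and the planned tests of gene lists (camera, fry and exact permutation tests of list means) and the planned averaging of probes of 1 gene were not run. The planned rule for named genes left out clone and contig names and so named none. In its place 4 probes are given by their identifier and sequence. They are the 2 largest rises and 2 largest falls among called probes whose groups did not overlap and which were well above background on all 8 arrays, a rule set after the data were examined.

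From the scanner files, log2 of the processed signal minus each array's 75th percentile over probes was computed. Control spots were left out and 215 spots marked as non-uniform or population outliers were set to missing. Their number per array was 9 ± 6.9 on river and 44.75 ± 16.8 on mesocosm arrays (mean ± SD, n = 4 each, two-sided exact permutation test, p = 0.0286). Probes well above background on at least 4 of the 8 arrays, whatever their group, were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the group as the term and Benjamini-Hochberg adjustment. A probe with an adjusted p under 0.05 is called. A log2 difference is mesocosm minus river throughout, and adjusted p-values are limma's. Where a probe was not well above background on any array of a group, its fold is a lower bound, set against the mean over that group's arrays of the higher of the probe's signal and the lowest signal among probes well above background. Single values per array were compared with a two-sided exact permutation test over the 70 arrangements of 8 arrays, whose smallest p is 0.0286. The number of arrays limits the precision, since each group holds 4 fish.

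All 4 river arrays lay on slide 1 and were read on scan day 1, and all 4 mesocosm arrays lay on slide 2 and were read on scan day 2. Batch and group cannot be told apart, and the planned fit with the slide as a block could not be made. The labels give the groups no shared replicate numbers, and the numbers used here only name the fish.

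Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, scaling on the median, no filter on dim probes, probes well above background on all 8 arrays, the series matrix values, an intensity trend in the prior variance, array weights, a test against a 1.2-fold change, outlier spots kept, and each fish left out in turn. Scaling on the spike-in transcripts, removal of each array's GC trend, normexp with an offset in proportion to the array's 75th percentile, and a restriction to probes well above the floor were added after seeing the data. The limma step was tested on simulated data for the comparison of mesocosm with river fish, with 12553 probes and 200 changed ones. At a log2 change of 0.5 it recovered 4% of the 50 changed probes, at 1 it recovered 52%, at 2 it recovered 92% and at 3 it recovered 94%, and 2.42% of the calls were false. With no change simulated it called 0 probes. The simulated noise was independent between probes and held no slide effect. Far fewer probes were changed than were called below, so these rates need not hold for the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.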

Results

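Ovarian transcripts were measured in 8 female largemouth bass collected in April, 4 from the St John River and 4 that had been placed in Apopka mesocosms. The series title gives the question as the effect of high contaminant loads in the mesocosms on the ovary. Of the 15208 probes, 11201 were well above background on all 8 arrays and 1413 on none. The number well above background was 12822 ± 504 in river fish and 12204 ± 491 in mesocosm fish (mean ± SD, n = 4 each), and the groups did not differ by an exact permutation test (p = 0.143). No probe was saturated. The 75th percentile of the processed signal was 1313 ± 349 intensity units on the river arrays and 4966 ± 1087 on the mesocosm arrays (n = 4 each, two-sided exact permutation test, p = 0.0286, the smallest possible). The scaling used below sets these percentiles equal. It moves all probes of an array by the same amount, so that slide differences that vary with signal level or transcript remain, as for the spike-in transcripts below.

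Arrays of mesocosm fish differed from those of river fish, which lay on another slide, at 3152 of the 12697 probes tested (24.8%). Of these, 1636 were higher and 1516 were lower in the mesocosm fish, a balance that turned with other scalings, as given below. At 2-fold or more, 859 probes were higher and 404 were lower, but with normexp and a fixed offset of 50, 313 were higher and 1051 lower. With normexp and an offset in proportion to each array, added after seeing the data, 417 were higher and 135 lower. At 4-fold or more, 216 were higher and 22 were lower, against 33 and 11 with the fixed and 55 and 4 with the proportional offset. Of the 4-fold calls, 12 rises and 9 falls had a group with no array well above background, so that their fitted size is not a measured fold. The median called rise was 1.04 log2 units and the median called fall had a size of 0.76 log2 units. The groups of 4 fish did not overlap at 3668 tested probes (28.9%, against 2.86% by chance).

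**Figure D1:**
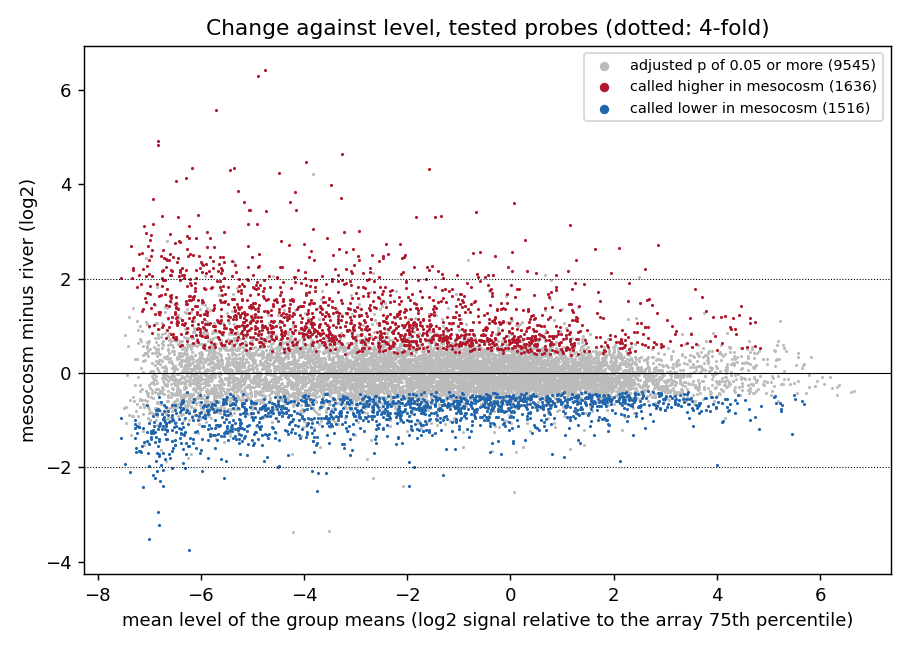
Each point is a tested probe, with the mean of its group means on the horizontal axis (log2 signal relative to the array's 75th percentile) and mesocosm minus river on the vertical axis (log2), and colours mark called rises, called falls and other probes. Of the calls beyond the dotted 4-fold lines, 216 lie above and 22 below.

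Among called probes well above background on all 8 arrays whose groups did not overlap, the largest rise was at UF_Msa_AF_103326 (60 bases, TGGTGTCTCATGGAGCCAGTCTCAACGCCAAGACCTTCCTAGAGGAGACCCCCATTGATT). Its log2 signal relative to the 75th percentile was -5.59 ± 0.65 in river fish and -0.94 ± 1.81 in mesocosm fish (SD, n = 4 each), a rise of 4.65 ± 0.78 log2 units (SE, adjusted p = 0.00447). Mesocosm fish 2 lay at -3.65, and the other 3 mesocosm fish lay between -0.07 and -0.002. Fitted differences above this one belonged to probes below background on some arrays and are not ranked.

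Probe UF_Msa_CF_127338 (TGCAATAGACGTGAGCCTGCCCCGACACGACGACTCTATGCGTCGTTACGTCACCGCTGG) rose by 4.33 ± 0.47 log2 units (SE, adjusted p = 0.00117). Its level was -3.74 ± 1.104 in river fish and 0.60 ± 0.22 in mesocosm fish (SD, n = 4 each). With normexp and an offset of 50 these rises were 3.21 and 3.53 log2 units, and both were still called. Their order turned there, with the proportional offset (3.67 and 3.82) and without mesocosm fish 4 (4.33 and 4.37).

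The largest falls under the same conditions were smaller. Probe UF_Msa_AD_200165 (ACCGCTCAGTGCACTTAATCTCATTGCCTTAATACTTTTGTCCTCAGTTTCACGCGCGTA) went from -2.48 ± 0.98 in river fish (SD, n = 4) to -4.99 ± 0.55 in mesocosm fish (SD, n = 3, after 1 outlier spot was set to missing). Its log2 difference was -2.51 ± 0.51 (SE, adjusted p = 0.0110), a 5.70-fold fall. With the outlier spot of mesocosm fish 2 kept, the difference was -2.17 (adjusted p = 0.0180). That fish then lay above river fish 3, so the groups did not overlap only with the spot left out. With normexp and the proportional offset the difference was -1.59 (adjusted p = 0.0231). Probe UF_Msa_AF_107496 (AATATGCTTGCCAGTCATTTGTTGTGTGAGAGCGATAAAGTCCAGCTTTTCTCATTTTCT) went from -0.76 ± 0.39 to -3.16 ± 1.01 (SD, n = 4 each). Its log2 difference was -2.39 ± 0.45 (SE, adjusted p = 0.00679), a 5.26-fold fall. Both of these probes were well above background on all 8 arrays. The deposited names of UF_Msa_AD_200165 and of both rises above carry a mark for the reverse complement, and that of UF_Msa_AF_107496 does not. UF_Msa_AD_200165 is the reverse-marked probe of a pair of the kind described in the third pattern below. Which strand these probes read was not tested. With spike-in scaling, added after seeing the data, the log2 differences were -1.07 for UF_Msa_AD_200165 and -0.92 for UF_Msa_AF_107496. The second was no longer called (adjusted p = 0.0515, from 0.000710 over its settings), in a setting whose p-values carry a shift shared by all probes of an array.

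**Figure D2:**
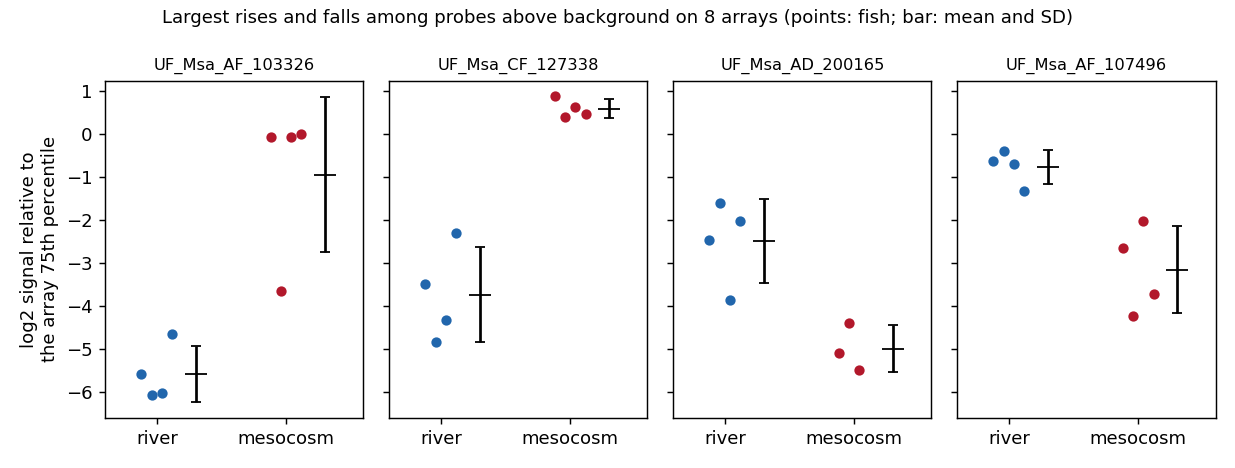
Points are fish and black bars are the mean and SD of each group, on the log2 scale relative to the array's 75th percentile, for the 2 largest rises and the 2 largest falls among probes well above background on all 8 arrays. Among the values shown, the fish of one group all lie above those of the other at each of the 4 probes. UF_Msa_AD_200165 has 3 mesocosm values, and its groups would overlap with the outlier spot kept.

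Some transcripts were measured in one group only. There were 97 probes well above background on all 4 river arrays and on no mesocosm array, of which 85 were called lower. Their bound on the fall reached 2-fold at 12 probes, with a median of 1.36-fold and a highest value of 4.87-fold. In the other direction 12 probes were well above background on all 4 mesocosm arrays and no river array, and all 12 were called higher. Each of these 12 rose by at least 2-fold, with a median bound of 4.39-fold and a highest bound of 23.2-fold. The lowest signal well above background lay at -7.47 ± 0.42 log2 units on the river arrays and at -6.69 ± 0.49 on the mesocosm arrays (SD, n = 4 each). A two-sided exact permutation test did not separate the groups (p = 0.0857). A higher level on the mesocosm arrays would leave less room to see a fall. Among calls of 4-fold or more that were well above background on at least 1 array of each group, 204 were rises and 13 were falls. When only probes well above background on all 8 arrays were tested, there were 91 such rises and 7 falls.

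The share of probes called varied with signal level. It was 35.7% in the dimmest decile of the tested probes, where many signals lay near the detection limit, 17.97% in the eighth decile and 22.8% in the brightest. The array carries 53 sequences on 2 probes each, and both copies were tested for 37 of them. The log2 differences of these copies correlated with r = 0.94 across pairs and differed by a median of 0.11 log2 units, and for 35 of the 37 pairs both copies or neither were called.

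The arrays of each group resembled each other more than those of the other group. Pearson correlations over the tested probes ran from 0.976 to 0.981 among river fish, from 0.977 to 0.982 among mesocosm fish and from 0.940 to 0.968 between groups. The first principal component held 50.04% of the variance and separated the groups, and the second held 11.9%. The median SD of a probe was 0.28 log2 units among river fish and 0.24 among mesocosm fish.

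Each group lay on a slide of its own with its own scan day, so these differences are between slides as much as between groups of fish and cannot be told apart from a slide effect. The titles of the river fish also carry a prefix that those of the mesocosm fish lack and whose meaning the labels do not give, and any difference it marks has the same limit. The counts depended on the offset and the scaling. With normexp and the fixed offset of 50, 1012 probes were higher and 3786 lower, in place of 1636 and 1516, the median probe moved from -0.03, which the scaling largely sets, to -0.23 log2 units, and rises made up 22.9% of the calls at 2-fold or more in place of 68.0%. Scaling on the spike-in transcripts, an alternative added after seeing the data, moved the median probe to 1.44 log2 units, so that 10783 probes were higher and 9 lower. These counts reflect a shift shared by all probes of an array rather than separate changes.

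The spike-in transcripts, which are foreign RNAs added to each labelling reaction, were measured as controls. Of the 10 on the array, 7 were well above background on all 8 arrays. Relative to the 75th percentile, the mean of these 7 was 2.15 ± 0.57 log2 units on river arrays and 0.67 ± 0.46 on mesocosm arrays (SD, n = 4 each, two-sided exact permutation test, p = 0.0286, the smallest possible). Without scaling, their mesocosm minus river differences ranged from -0.12 to 1.68 log2 units. The slope of log signal against log spike-in amount was 0.850 ± 0.044 on river arrays and 1.01 ± 0.01 on mesocosm arrays (SD, n = 4 each, exact permutation p = 0.0286).

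**Figure D3:**
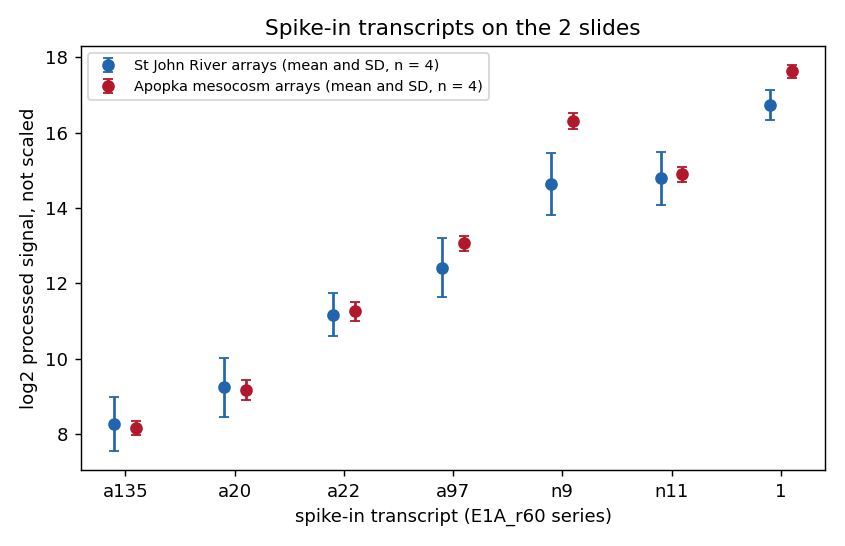
Mean and SD over 4 arrays of the unscaled log2 processed signal of the 7 detectable spike-in transcripts, ordered by their river mean. The gap between the slides differs between transcripts, from -0.12 log2 units (a135) to 1.68 log2 units (n9).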

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

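The tests by splits of the arrays, by spike-in transcripts and by level-matched random lists were chosen after the results they bear on were seen. The settings with the GC trend removed, above the floor and with the proportional offset were also added after seeing the data, and only the bounds that decide them were set before their values were computed. No biological explanation other than the group itself was tested.

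Along the first principal component, Apopka mesocosm fish 1 lay apart from the other fish of its group, at 50.3 against 33.71 to 36.55. At probe UF_Msa_AF_103326, Apopka mesocosm fish 2 lay apart at -3.65 log2 units, against -0.07 to -0.002 in the others of its group. These were 2 of 23 groups of 4 values tested, and chance gives about 1 in 20. The control spots below met a criterion that was widened after their values were seen, since no control probe was well above background on mesocosm arrays alone. Control probe DCP_20_9, which the comparison leaves out, was brighter on every mesocosm array than on every river array, by 2.85 log2 units relative to the 75th percentile, and was well above background on 4 mesocosm arrays and 1 river array. The bright corner spots were higher by 1.77 log2 units on the same scale.

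The first pattern is the number of probes called between the groups. Chance is argued against but not excluded. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, reached 3152 calls, and the highest other split called 1. First of 35 is the most extreme rank this test allows. The other splits mix the slides, so a slide difference alone would also give this result. For calls of 2-fold or more (1263) and of 4-fold or more (238) it was again 1 split of 35, with 1 call in the highest other. These calls are a part of the 3152, and no other split called more than 1 probe in all. Their result therefore follows from the first and adds no further test. GC content of the probe is argued against as the whole cause, since 94.1% of the called probes were still called once each array's GC trend was removed. A slide, hybridization or scan difference stays open: the differences of the 7 detectable spike-in transcripts between the slides had an SD of 0.657 log2 units after their common shift was removed, although another lot of the spike-in mix could give the same spread without touching the fish transcripts. Each group has its own slide, so that a share of the calls may come from the slide, and the difference between mesocosm and river fish stays open beside it.

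The second pattern is that large rises outnumber large falls, with rises making up 90.8% of the calls at 4-fold or more. A higher background floor on the mesocosm arrays could hide falls. Among probes at least 4 log2 units above the higher floor, rises made up 93.9% of 99 such calls (95% exact interval 87.3% to 97.7%). This share was not below the 90.8% among all tested probes, which argues against the floor as the whole cause. With normexp in place of the processed signal, and an offset in proportion to each array's 75th percentile, rises were 93.2% of 59 such calls (95% exact interval 83.5% to 98.1%). With the planned fixed offset of 50 they were 75% of 44 (59.7% to 86.8%). These exact intervals treat called probes as independent and do not cover the spread between fish or slides. The interval with the proportional offset lies above the preset bound of 75%. Normexp was run with the local background, which it also subtracts, so this result cannot decide whether subtraction causes the pattern. With the proportional offset, the excess of rises at 4-fold remained without the trend removal and surrogate values of the processed signal. The interval with the fixed offset does not lie above the bound. At 2-fold the fixed offset turned the share of rises to 22.9%, so that a part played by the offset stays open. A slide difference and a difference between the groups of fish were not tested for this pattern.

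The third pattern concerns 202 pairs of probes that carry the name of 1 sequence with and without a mark for the reverse complement. Where both were well above background on at least 4 arrays and lay 8-fold or more apart in mean signal (76 pairs), the median log2 difference of the dimmer probes was -0.65 and that of the brighter probes was 0.03. The median change of the dimmer minus the brighter probe was -0.63, but -1.06 with the fixed and -0.39 with the proportional offset. Signal level is argued against, since 95% of 10000 random lists of other probes matched on level had medians between -0.18 and 0.21. The lists treat probes as independent and do not cover the spread between fish. Per fish, the median dimmer minus brighter signal was -6.97 ± 0.13 in river and -7.20 ± 0.13 in mesocosm fish (SD, n = 4 each), which an exact permutation test did not separate (p = 0.0857). The median over pairs is taken within each fish here, so the group difference of -0.23 is another measure than the median change of -0.63. Whether the dimmer probes read antisense transcripts, side products of labelling or cross-hybridization was not tested, and a slide difference stays open.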

How the results depend on the processing

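The settings on spike-in transcripts, GC trend, proportional offset and the floor were chosen after seeing the data. Signal over background and 4 fish per group limit these counts. Of 264 values recomputed over 22 settings, 224 kept their direction and call, or for counts and shares stayed within 1.5 times or the interval, 38 moved, 1 turned direction and 1 lost its call. Kept calls can still differ in size: the rises of UF_Msa_AF_103326 and UF_Msa_CF_127338 were 3.21 and 3.53 log2 units with normexp and an offset of 50, and UF_Msa_AD_200165 fell by 1.07 with spike-in scaling. With normexp and an offset of 50 there were 4798 calls (1012 higher, 3786 lower), 44 of them at 4-fold, and rises made up 22.9% of the calls at 2-fold in place of 68.0%, and 75% at 4-fold. Of its calls 2348 were shared with the reported 3152, 2227 of them in the same direction. With normexp and an offset in proportion to each array, 552 probes were called at 2-fold (75.5% rises) and 59 at 4-fold, so the fixed offset, a larger part of the signal on the dimmer river arrays, is a candidate cause of the turn towards falls. Against a 1.2-fold change 1357 were called, 854 higher and 503 lower. Spike-in scaling, which moves all probes of an array by 1 value, gave 10792 calls (10783 higher, 9 lower), 10351 at 2-fold (99.92% rises) and 2264 at 4-fold (99.91% rises), and the fall of UF_Msa_AF_107496 lost its call (log2 difference -0.92, adjusted p = 0.0515, from 0.000710 over its settings). Rises at 2-fold were 60.1% with quantile normalization, 60.7% with the median, 61.6% with the series matrix values and 71.0% with no filter, and at 4-fold 82.4% with quantile normalization and 86.0% with the series matrix values. With fewer probes tested, those well above background on all 8 arrays gave 98 calls at 4-fold and 74.2% rises at 2-fold, and those above the floor gave 706 calls at 2-fold (72.4% rises) and 99 at 4-fold. The cause of the other moves was not tested. Scaling on the median moved the median probe to -0.10 log2 units.

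Leaving out 1 fish at a time gave 2189 to 2685 calls, 1211 to 1557 higher and 975 to 1214 lower, 1055 to 1347 at 2-fold (64.5% to 72.4% rises) and 190 to 298 at 4-fold (86.5% to 92.6% rises). The 975, against 1516, came without Apopka mesocosm fish 1. The slide as a block, the mean of a gene's probes, camera and fry were not run. No paired analysis was possible because the fish share no replicate numbers in the labels. The median change of the dimmer minus the brighter strand, -0.63, was negative in all 22 settings. It ran from -1.06 with normexp and an offset of 50, and -1.01 above the floor (31 pairs), to -0.39 with the proportional offset. Some settings could not change it: scaling on the median or the spike-ins cancels within an array. The prior trend, the 1.2-fold test and the lack of a filter leave the differences of these pairs as they are.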

Other observations

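Some probes varied widely between fish of the same group. With signals raised to the lowest level well above background on each array, and each sequence counted once, the fish of each group spanned 8-fold or more at 25 tested probes, of which 8 spanned 16-fold or more in both groups. Among river fish 105 probes spanned 8-fold or more and among mesocosm fish 96. River fish had the larger SD at 57.7% of the tested probes.

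The probe identifiers fall into 3 classes by name, whose meaning the files do not give. Of the tested probes, 38.5% of 244 were called in class AD, 21.6% of 6748 in class AF and 28.0% of 5705 in class CF, with 52 rises and 42 falls, 741 and 719, and 843 and 755. Across probes, which are not independent replicates, the log2 difference fell weakly with GC content (Spearman's rho = -0.12). The 52 probes with at most 30% GC had a median log2 difference of 0.87. Of the 202 pairs that carry 1 sequence name with and without the reverse mark, 87 had both probes well above background on at least 4 arrays, 79 had 1 and 36 had neither. In 42 pairs the probes overlapped by at least 25 bases, all on opposite strands.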
